A study of Mus musculus with 36 samples.

How the data were processed

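RNA sequencing values of 33 libraries from 36 listed samples were analysed, in the 11 groups given by the labels. Mouse embryonic fibroblasts carried a fluorescent reporter of the Nrl promoter. Intermediates, reprogrammed cells and rods were taken as described in the results. Cells were sorted by reporter expression and 80 ng of total RNA was used per sample, per the labels' protocols. The other 3 samples, rods of P3, have no column in the table and were not analysed here. Rods of P2, P4, P6, P10, P14 and P28 were reused from an older series, per the labels. For P10 replicate 3 and P14 replicate 3 the labels list no older sample.

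Reads were quantified with kallisto, per the submitters' processing notes. Its version, its index and the genome build are not given in the sources used here, nor is the strand of the library kit, so genes that overlap on opposite strands could not be told apart. The deposited table holds a normalized CPM signal per gene and library, which the authors scaled between libraries by a method not given in the sources used here. Column sums differ from library to library and the values are not whole. The counts behind them are unknown, so the depth per sample and the precision it gives are not known, and no count model was fitted. The table holds 15289 genes, each with a CPM of at least 0.593 in its third-largest library. All 33 value columns were used and 0 were left unused. Of the genes, 99.05% matched GENCODE M21 (GRCm38) by identifier, which gave coordinates, GC content and transcript length. The symbol of 101 genes repeats that of another gene, and each Ensembl gene was tested on its own.

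Values were analysed as deposited, as log2(CPM + 1). Genes with a CPM of at least 1 in at least 3 libraries of a fit, or 2 where the smallest group has 2, were tested. Groups were compared with limma 3.58.1 in R 4.3.3, using a linear model per group and moderated variances with a mean trend. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2 on that scale, so folds of genes near 0 CPM are shrunk. Fits compared CiPC with MEF, day 5 with MEF, day 8 with day 5, CiPC with day 8, CiPC with P5 rods, P5 rods with MEF and P28 with P2 rods. Rod age was fitted as a slope on log2 age over P2, P4, P6, P10, P14 and P28, given as the change over the whole range. P5 rods were also compared with the mean of P4 and P6. Comparisons planned with P3 and P5 rods used P5 alone. The comparison between series had been planned with P2, P4 and P6 on the older side. Without P3, the mean of P4 and P6 was used, because it has the mean age of P5. P5 alone against the planned older side of P2, P4 and P6 was added as an alternative after the data were seen.

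Gene lists for cell types, pathways and technical states (41 in all) and the naming rule were fixed before the data were examined. So were the tests and alternatives, except those named in the text as changed or added later. Lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Members were also counted with p adjusted over the list alone. Shared changes of CiPC and P5 rods were compared with 100 simulations of unchanged groups set against the same simulated MEF means. The simulated spread was that within groups, pooled over MEF, CiPC and P5 rods. The 200 genes with the strongest rise and the 200 with the strongest fall in the age slope served as rod-age sets.

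Named genes followed a rule. The anchor genes are always given. Some genes that the rule names are not reported here, and no other gene took their place. For a list described, up to 4 members with the largest changes past the threshold are eligible, together with any that moved against it. For each comparison, the 5 genes that rose and the 5 that fell most are given, among genes at a mean of at least 10 CPM in a group and with no overlap between the replicates of the groups. Predicted genes with numbered names were left out of that choice. Genes with near-identical copies, such as Eno1b, Mup7 and the ribosomal protein genes, are uncertain, because the table does not show how shared reads were divided.

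The procedure was tested on simulated data with 200 changed genes. These were drawn from genes well above the expression filter, so recovery of genes near the filter was not assessed. At folds of 3, 5 and 10 it recovered at least 98.5% in 7 of the comparisons, and 89.6%, 95.5% and 100% in P28 against P2 and in the age slope. It called 0 to 6 unchanged genes and 0 of 40 unchanged lists. Alternatives covered the pseudocount, the filter, quantile and median-of-ratios scaling, the variance prior, the fold threshold, the replicate number as a block, the rods used and each library left out. Trends on GC content and transcript length were removed with loess (span 0.5). Random draws used the seed 1. Reference tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.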

Results

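Gene expression was measured by RNA sequencing in 33 libraries of mouse cells carrying a green fluorescent protein reporter under the promoter of Nrl, the transcription factor that specifies rods. Mouse embryonic fibroblasts at passage 2 (MEF, n = 3) were the starting cells. Cells under treatment with 5 chemicals in photoreceptor induction medium were taken as intermediates at day 5 (n = 3) and day 8 (n = 3) and as reprogrammed photoreceptor-like cells, here CiPC, at day 11 (n = 3). Rods isolated from the retina at postnatal days 2 (n = 2), 4 (n = 2), 5 (n = 3), 6 (n = 3), 10 (n = 4), 14 (n = 3) and 28 (n = 4) served as the reference and are written P2 to P28. The P5 rods belonged to the same series as the cultured cells, and the other rods were reused from an older series, although for P10 replicate 3 and P14 replicate 3 the labels list no older sample.

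The table held 15289 genes in the authors' normalized CPM. Column sums ran from 719752 in P2 replicate 1 to 2277242 in P28 replicate 2, values were not whole, and the sequencing depth behind them is unknown. The share of CPM in the 10 most abundant genes ran from 3.39% in P5 replicate 3 to 30.8% in P28 replicate 2. Mitochondrially encoded genes took 1.96% (P5 replicate 3) to 19.1% (P10 replicate 2) of a library. The labels do not say that replicates came from separate cultures or animals, so each p-value measures the spread between these samples, which may be technical.

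The first principal component of log2(CPM + 1) carried 62.7% of the variance and parted the cultured cells from the rods, with CiPC between them. MEF lay at -161.21 to -159.87, day 5 cells at -173.14 to -172.27, day 8 cells at -171.84 to -168.58 and CiPC at -79.635 to -76.544. P5 rods lay at 52.92 to 54.844 and P28 rods at 135.87 to 137.89. Across genes, the mean correlation of CiPC libraries was 0.825 with MEF, 0.823 with P2 rods, 0.794 with P5 rods and 0.661 with P28 rods. With day 5 and day 8 cells it was 0.7938 and 0.7765, below that with MEF. On the second component, P10 replicate 4 stood at 21.389, apart from the other P10 libraries at -21.985 to -8.9167, and P14 replicate 3 at -14.339 against -44.037 and -37.507. These 2 libraries also had fewer mitochondrial transcripts than the others of their age, 3.87% against at least 11.8% at P10 and 3.95% against at least 7.92% at P14.

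**Figure D1:**
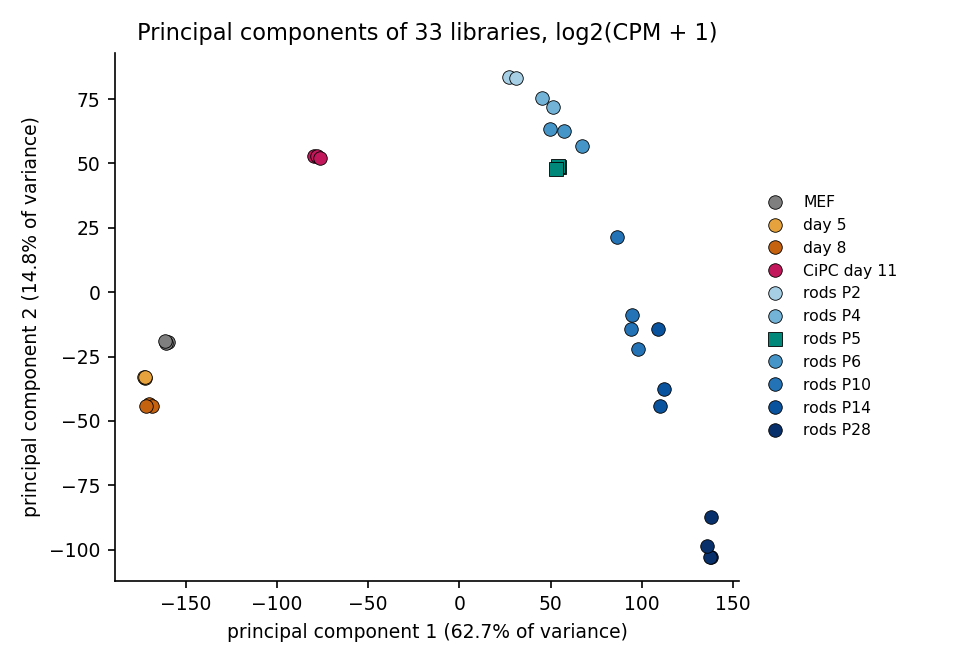
Each point is 1 of the 33 libraries, with the first principal component of log2(CPM + 1) (62.7% of variance) on the x axis and the second (14.8%) on the y axis, coloured by group. CiPC lie at -79.635 to -76.544 on the first component, between the day 8 cells and the P2 rods.

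The anchor genes were fixed before the data were examined (GRCm38 coordinates, all protein-coding; levels are mean ± SD). Nrl (chromosome 14, 55518978 to 55524981, minus strand) was at 0.237 ± 0.0582 CPM in MEF, 0.155 ± 0.0935 at day 8 and 30.7 ± 0.282 in CiPC. In P5 rods it was at 896 ± 38.6 CPM and in P28 rods at 10111 ± 1901. Crx (chromosome 7, 15865947 to 15879968, minus strand), the photoreceptor homeobox factor, was at 0.391 ± 0.197 CPM in MEF, 93 ± 5.68 in CiPC and 1664 ± 45.8 in P5 rods. Nr2e3 (chromosome 9, 59942771 to 59960659, minus strand), a nuclear receptor that represses cone genes, was at 20.8 ± 0.546 CPM in CiPC, 557 ± 31 in P5 rods and 1763 ± 257 in P6 rods. Sag (chromosome 1, 87803680 to 87845158, plus strand), rod arrestin, was at 90.4 ± 1.5 CPM in CiPC and 649.6 ± 16.1 in P5 rods. Rcvrn (chromosome 11, 67695326 to 67703333, plus strand), recoverin, was at 17.3 ± 1.14 CPM in CiPC, 15.2 ± 0.457 in P2 rods and 269 ± 19 in P5 rods.

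CiPC levels were 4.44% of P2, 3.42% of P5 and 0.303% of P28 rods for Nrl. For Rcvrn the same shares were 114%, 6.44% and 0.307%. Axin2 (chromosome 11, 108920349 to 108950783, plus strand), a negative regulator and target of Wnt signalling, was at 6.11 ± 1.2 CPM in MEF, 21.6 ± 0.557 at day 5, 8.38 ± 2.08 at day 8 and 5.01 ± 1.54 in CiPC. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand), a chain of type I collagen, was at 4545 ± 622 CPM in MEF, 9580 ± 2067 at day 8 and 41.2 ± 13.6 in CiPC. Thy1 (chromosome 9, 44043384 to 44048579, plus strand), a fibroblast and neuron surface protein, was at 121 ± 4.43 CPM in MEF and 2.0 ± 0.0259 in CiPC.

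**Figure D2:**
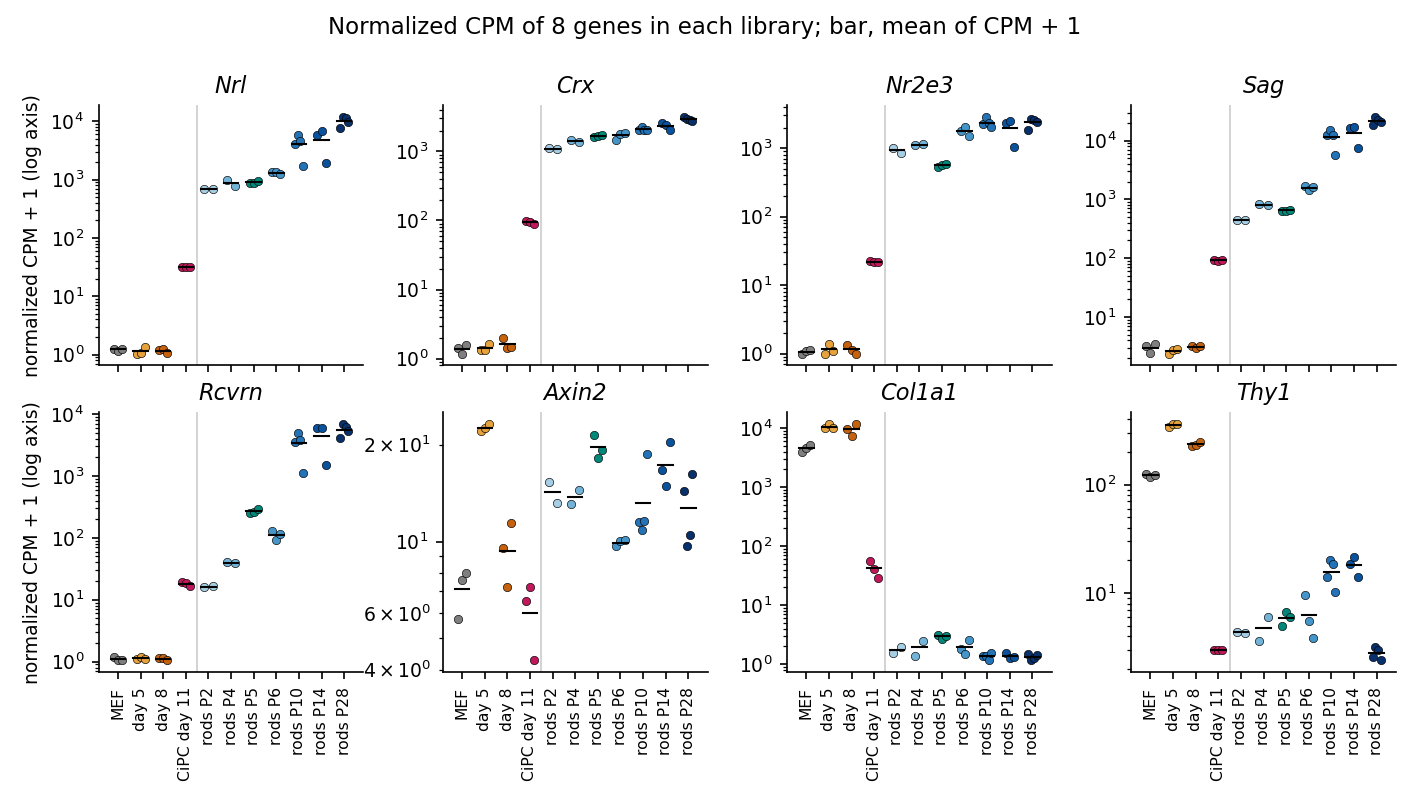
Each panel shows 1 anchor gene, with CPM + 1 on a log axis and the 11 groups along the x axis; points are libraries and bars are group means. Nrl stands at 30.7 ± 0.282 CPM in CiPC against 896 ± 38.6 in P5 rods.

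The comparison of CiPC with MEF asked how the end point of the chemical treatment differed from the starting fibroblasts. Genes of rods, retinal progenitors and Müller glia were higher in CiPC, and genes of fibroblasts, contractile cells and muscle were lower. Crym, a thyroid hormone-binding protein, was at 3113 ± 73.4 against 1.84 ± 0.355 CPM (mean ± SD, n = 3 in each group). Its change was 10.10 ± 0.11 (± SE, in log2 units on the log2(CPM + 1) scale, as all changes here). Npvf, the precursor of RFamide neuropeptides, rose by 9.34 ± 0.10 and Cp, the copper-carrying ferroxidase ceruloplasmin, by 8.64 ± 0.079. Lcn2, which binds iron-carrying siderophores, rose by 8.46 ± 0.073 and Scg2, a secretory granule protein, by 7.87 ± 0.11. Pappa, a protease of insulin-like growth factor binding proteins, changed by -8.13 ± 0.079 and Inhba, a subunit of activin, by -7.56 ± 0.054. Lox, which crosslinks collagen, was at 10.5 ± 0.416 against 1815 ± 70.9 CPM. Il1rl1, the receptor of interleukin 33, changed by -7.28 ± 0.11. Eno1b changed by -7.92 ± 0.20, but it is a near-identical copy of Eno1, so its value is uncertain.

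In the rod phototransduction and outer segment list, 26 of 29 members rose and 3 did not pass (camera over tested members, adjusted p = 2.91e-10). Pdc, phosducin, rose by 6.02 ± 0.12. Prph2, a disc rim protein, was at 56.1 ± 6.92 against 0.228 ± 0.106 CPM and Rp1, of the outer segment axoneme, at 49.2 ± 4.17 against 0.364 ± 0.0949 CPM. Among photoreceptor transcription factors, 11 of 12 members rose and 1 did not pass (adjusted p = 8.92e-06), with Otx2 at 74.1 ± 1.56 against 0.228 ± 0.051 CPM and Rorb at 69.9 ± 5.82 against 0.758 ± 0.3 CPM. For Müller glia genes, 10 of 12 members rose and 2 did not pass (adjusted p = 2.7e-06). Rlbp1, which carries retinaldehyde, was at 263 ± 8.54 against 0.247 ± 0.214 CPM. Slc1a3, a glutamate transporter, was at 955 ± 46.7 against 5.16 ± 1.73 CPM and Kcnj10, a potassium channel, at 108 ± 2.69 against 0.378 ± 0.112 CPM. Retinal progenitor genes changed likewise, and 11 of 12 members rose and 1 did not pass (adjusted p = 9.29e-06). Pax6 was at 161 ± 5.32 against 1.06 ± 0.128 CPM and Six6 at 45.8 ± 4.52 against 0.141 ± 0.105 CPM. Of the bipolar cell list, 9 of 10 members rose and 1 did not pass (adjusted p = 7.79e-05). Grm6, the glutamate receptor of ON bipolar cells, was at 35.6 ± 1.11 against 0.0828 ± 0.0809 CPM and Trpm1, the channel it controls, at 23.8 ± 1.0 against 0.371 ± 0.187 CPM.

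For cone genes, 7 of 10 members rose, 1 fell and 2 did not pass (adjusted p = 0.0189, and adjusted p = 0.0542 with an estimated correlation). Gnb3 and Gnat2, cone transducin subunits, changed by 7.28 ± 0.13 and 2.14 ± 0.16, and Pde6h, the cone phosphodiesterase gamma subunit, by -1.02 ± 0.14. Among photoreceptor synapse genes, 10 of 13 members rose, 1 fell and 2 did not pass (adjusted p = 0.00014). Syp, synaptophysin, rose by 5.75 ± 0.13, while Elfn1 changed by -2.39 ± 0.22. Of the proneural factors, 8 of 11 members rose and 3 did not pass (adjusted p = 0.000337). Of the primary cilium transport genes, 8 of 20 members rose and 12 did not pass (adjusted p = 0.00101). In the cell cycle list, 18 of 26 members rose and 8 did not pass (adjusted p = 2.56e-08). Mki67 was at 407 ± 26.8 against 77.3 ± 2.86 CPM and Top2a at 293 ± 18.9 against 69.6 ± 2.56 CPM. Cholesterol synthesis genes were higher in CiPC, and 15 of 17 members rose and 2 did not pass (adjusted p = 4.53e-06), led by Dhcr7 (2.53 ± 0.089). For interferon-stimulated genes, 7 of 17 members rose, 1 fell and 9 did not pass (adjusted p = 0.00344). Oasl2 changed by 4.16 ± 0.13 and Ifi44 by -1.32 ± 0.19.

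In the fibroblast and mesenchymal list, 24 of 30 members fell and 6 did not pass (adjusted p = 6.66e-12). Postn, an extracellular matrix protein, was at 2.29 ± 0.615 against 398 ± 4.16 CPM and Col1a2 at 26.1 ± 3.93 against 3210 ± 191 CPM. Of the contractile and myofibroblast list, 10 of 12 members fell and 2 did not pass (adjusted p = 2.32e-06). Des was at 0.721 ± 0.107 against 204 ± 9.75 CPM and Myh11 at 1.3 ± 0.176 against 105 ± 0.668 CPM. MEF also held transcripts of skeletal muscle, macrophages and epithelia, which were lower in CiPC. Among muscle genes, 11 of 12 members fell and 1 did not pass (adjusted p = 1.54e-05), with Acta1, skeletal actin, at 1.88 ± 0.7 against 199 ± 14.5 CPM. Among macrophage and leukocyte genes, 9 of 14 members fell and 5 did not pass (adjusted p = 0.00248), with C1qa, a complement component, at 3.09 ± 0.785 against 37.3 ± 3.17 CPM. Among epithelial genes, 1 of 6 members rose and 5 fell (adjusted p = 0.013, and adjusted p = 0.0501 with an estimated correlation), and the member that rose was Cdh1 (1.34 ± 0.14). Of the p53 and cell cycle arrest genes, 1 of 14 members rose, 11 fell and 2 did not pass (adjusted p = 0.000127). Cdkn1a, the p21 inhibitor, was at 75.3 ± 0.386 against 1146 ± 25.9 CPM, and Cdkn1b, the p27 inhibitor, rose by 2.55 ± 0.07. Of the TGF-beta response genes, 1 of 16 members rose, 12 fell and 3 did not pass (adjusted p = 0.00151, and adjusted p = 0.0501 with an estimated correlation). Id2 rose against the list (1.41 ± 0.068). The unfolded protein and integrated stress response list lost its call under quantile normalization (adjusted p = 0.0823), where on the deposited values 6 of 16 members fell and 10 did not pass (adjusted p = 0.00347, and adjusted p = 0.0628 with an estimated correlation). So did the ribosomal protein genes, which have near-identical pseudogenes (adjusted p = 0.0823), of which 8 of 20 members fell and 12 did not pass (adjusted p = 5.21e-05, and adjusted p = 0.0501 with an estimated correlation).

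For the remaining 18 of the 39 lists, camera's adjusted p lay above 0.05. Members that rose and fell numbered 7 and 3 of 15 for pan-neuronal genes (adjusted p = 0.0767) and 5 and 2 of 10 for amacrine, horizontal and ganglion cells (adjusted p = 0.345). Pigment epithelium had 1 and 0 of 4 (adjusted p = 0.974) and glial and Schwann cells 3 and 3 of 8 (adjusted p = 0.888). Endothelium had 1 and 2 of 9 (adjusted p = 0.666), adipocytes 0 and 0 of 11 (adjusted p = 0.678) and cartilage and bone 3 and 3 of 9 (adjusted p = 0.808). Among signalling lists, the numbers were 5 and 2 of 15 for cAMP and CREB targets (adjusted p = 0.256) and 6 and 6 of 24 for NF-kB targets (adjusted p = 0.386). Hedgehog targets had 1 and 4 of 7 (adjusted p = 0.386), retinoic acid targets 3 and 4 of 11 (adjusted p = 0.826) and canonical Wnt targets 3 and 1 of 10 (adjusted p = 0.87). For 3 metabolic lists a call appeared under quantile normalization alone. These were oxidative phosphorylation with 0 and 0 of 22 (adjusted p = 0.094; adjusted p = 0.00326 under quantile normalization), glycolysis with 3 and 2 of 21 (adjusted p = 0.633; 0.0064) and NRF2 and antioxidant genes with 2 and 0 of 17 (adjusted p = 0.171; 0.0288). Histone genes had 5 and 2 of 8 (adjusted p = 0.114), immediate early genes 5 and 3 of 16 (adjusted p = 0.199) and housekeeping genes 0 and 2 of 13 (adjusted p = 0.819).

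With limma, 2272 of the 14347 genes tested were higher in CiPC than in MEF and 2369 were lower (adjusted p under 0.05 and a fold of at least 2). Counts adjusted over the list alone equalled those over all genes in each of the 39 lists, and 16 of the 21 called lists kept their call with an estimated correlation. No called list changed direction under quantile or median-of-ratios scaling. The median, the mean and the test of a list differed in sign only in lists without a call, in this and every other comparison. Here these were glycolysis, endothelium, adipocytes, cartilage and bone, canonical Wnt targets and pigment epithelium.

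The day 5 cells were compared with MEF as the earliest step of the time course. Contractile, TGF-beta response and macrophage genes were lower at day 5, and interferon-stimulated and adipocyte genes were higher. Saa3, an acute-phase serum amyloid, was at 12179 ± 131 against 3.26 ± 0.487 CPM (n = 3 each). Agtr2, an angiotensin receptor, rose by 10.56 ± 0.12 and Dpt, the matrix protein dermatopontin, by 9.53 ± 0.086. C3, complement component 3, rose by 8.02 ± 0.11 and Draxin, an axon guidance protein, by 7.97 ± 0.10. Ctgf, a connective tissue growth factor, was at 9.92 ± 0.398 against 2385 ± 33.9 CPM and Cnn1, calponin, at 2.34 ± 0.258 against 440.2 ± 17.8 CPM. Tagln, transgelin, was at 37.1 ± 2.06 against 3715 ± 75.7 CPM, and Col8a1 changed by -6.94 ± 0.065.

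In the contractile list, 11 of 12 members fell and 1 did not pass at day 5 (camera, adjusted p = 3.82e-06). TGF-beta response genes were lower, and 11 of 16 members fell and 5 did not pass (adjusted p = 2.97e-05). Of the macrophage and leukocyte list, 12 of 14 members fell and 2 did not pass (adjusted p = 3.43e-06), with C1qa at 0.902 ± 0.124 against 37.3 ± 3.17 CPM. In the fibroblast list, 15 of 30 members rose, 6 fell and 9 did not pass (adjusted p = 0.0145). Pdgfra was at 1179 ± 23.2 against 9.01 ± 3.12 CPM and Dcn, decorin, at 4770 ± 121 against 73.8 ± 1.7 CPM. The members that fell were Fn1, S100a4, Lox, Vim, Loxl2 and Fbln2. Among interferon-stimulated genes, 12 of 17 members rose and 5 did not pass (adjusted p = 9.11e-05), with Ifit1 at 15.4 ± 0.732 against 1.14 ± 0.457 CPM. Among NF-kB targets, 13 of 24 members rose, 3 fell and 8 did not pass (adjusted p = 0.00139). Cxcl5, a chemokine, rose by 6.33 ± 0.09, and Ptgs2, Il6 and Ccl20 moved against the list. Of the adipocyte list, 7 of 11 members rose and 4 did not pass (adjusted p = 0.000355). Lpl, lipoprotein lipase, was at 1149 ± 7.59 against 19.1 ± 1.03 CPM and Pparg, the adipocyte nuclear receptor, at 21.2 ± 1.78 against 0.886 ± 0.142 CPM.

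Other lists called higher at day 5 had 6 of 26 cell cycle genes past the threshold (adjusted p = 7.38e-05), 6 of 17 cholesterol synthesis genes (adjusted p = 0.000259) and 6 of 20 cilium genes (adjusted p = 0.00782). Among epithelial genes, 5 of 6 members fell and 1 did not pass (adjusted p = 0.00749). Of the unfolded protein and stress response genes, 1 of 16 members rose, 7 fell and 8 did not pass (adjusted p = 0.000649). Trib3 changed by -4.19 ± 0.11 and Slc7a11, a cystine transporter, by 2.94 ± 0.082. For 3 further lists, a call with the preset correlation was lost both with an estimated correlation and under quantile normalization. In the p53 list, 2 of 14 members rose, 5 fell and 7 did not pass (adjusted p = 0.0425, and adjusted p = 0.164 with an estimated correlation; 0.0571 under quantile normalization). Müller glia had 4 of 12 members that rose (adjusted p = 0.0431, and adjusted p = 0.102 with an estimated correlation; 0.0618), and 4 of 13 housekeeping genes fell (adjusted p = 0.0479, and adjusted p = 0.104 with an estimated correlation; 0.247). The rod list was not called, and 1 of 29 members rose, 1 fell and 27 did not pass (adjusted p = 0.668). With limma, 2006 genes were higher at day 5 and 1867 lower (1762 and 1908 under quantile normalization), and 12 of the 15 called lists kept their call with an estimated correlation. Counts adjusted over the list alone equalled those over all genes, and no called list changed direction under another scaling.

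Between day 5 and day 8, the second step, most adipocyte genes rose, and some contractile and TGF-beta response genes fell. Ucp1, the uncoupling protein of thermogenic fat, was at 119.8 ± 2.65 against 0.0502 ± 0.0435 CPM at day 8 and day 5 (n = 3 each). Elovl3, a fatty acid elongase, rose by 5.75 ± 0.11, Gpd1, glycerol-3-phosphate dehydrogenase, by 5.41 ± 0.13 and Pck1, a gluconeogenic enzyme, by 5.24 ± 0.10. Mup7, of a family of near-identical major urinary proteins and so uncertain, changed by 5.10 ± 0.11. Tnc, tenascin C, was at 73.2 ± 1.81 against 628 ± 3.75 CPM, and Col12a1, a collagen chain, changed by -3.50 ± 0.079. Megf6 changed by -3.03 ± 0.17, Syt13 by -2.97 ± 0.076 and Moxd1 by -2.63 ± 0.10.

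In the adipocyte list, 9 of 11 members rose and 2 did not pass (camera, adjusted p = 1.73e-12). Adipoq, adiponectin, was at 63.1 ± 1.29 against 2.67 ± 0.383 CPM and Plin1, perilipin, at 226 ± 32.3 against 12.7 ± 1.12 CPM. Of the oxidative phosphorylation genes, 3 of 22 members rose and 19 did not pass (adjusted p = 4.12e-12), with Cycs, cytochrome c, at 79.6 ± 3.81 against 23 ± 6.23 CPM. The contractile list was again called lower, and 5 of 12 members fell and 7 did not pass (adjusted p = 1.13e-06), with Acta2 at 72.4 ± 2.77 against 334 ± 10.7 CPM. For TGF-beta response genes, 6 of 16 members fell and 10 did not pass (adjusted p = 7.39e-05), with Thbs1 at 487 ± 9.7 against 2378 ± 25.7 CPM. For canonical Wnt targets, 4 of 10 members fell and 6 did not pass (adjusted p = 0.000793, and adjusted p = 0.0772 with an estimated correlation), Lgr5 by -2.06 ± 0.13 and Axin2 by -1.29 ± 0.20. Interferon-stimulated genes were called higher, and 3 of 17 members rose and 14 did not pass (adjusted p = 0.000407). Macrophage genes were called higher with 1 of 14 members rose and 13 did not pass (adjusted p = 0.0028), and NF-kB targets lower with 1 of 24 members rose, 1 fell and 22 did not pass (adjusted p = 0.00237).

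The other called lists of this step had few members past the threshold. Among those called higher, 1 of 17 NRF2 genes passed (adjusted p = 2.17e-06). The other lists called higher lost the call with an estimated correlation (adjusted p = 0.0582 to adjusted p = 0.182). They were the cell cycle with 0 of 26 members past the threshold, immediate early genes with 3 of 16, the stress response with 1 of 16, glycolysis with 1 of 21 that fell, housekeeping genes with 1 of 13 and Müller glia with 3 of 12. The lists called lower and lost likewise (adjusted p = 0.0582 to adjusted p = 0.211) were ribosomal proteins with 0 of 20, endothelium with 3 of 9, fibroblasts with 2 of 30, muscle with 4 of 12, epithelium with 1 of 6 and Hedgehog targets with 2 of 7. Ckm rose against the muscle list. Epithelium and Hedgehog targets also lost the call under quantile normalization (adjusted p = 0.0775 and adjusted p = 0.0775). With limma, 479 genes were higher at day 8 and 399 lower, and 8 of the 21 called lists kept their call with an estimated correlation. The number of genes depended on the pseudocount, with 1369 called at 0.1, more of them lower than higher, and 553 at 3. No called list changed direction under another scaling, and counts adjusted over the list alone equalled those over all genes.

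CiPC were then compared with day 8 cells, the last step of the treatment. Rod, progenitor and Müller glia genes were higher in CiPC, and fibroblast and adipocyte genes were lower. The reprogrammed cells were sorted by the reporter, and Nrl was at 0.155 ± 0.0935 CPM at day 8. A change over time and the selection of cells therefore cannot be told apart here, nor in the comparison of CiPC with MEF. Crym was at 3113 ± 73.4 against 0.598 ± 0.188 CPM and Npvf at 690.2 ± 21.3 against 0.0308 ± 0.0534 CPM (n = 3 each). Col9a1, a cartilage and vitreous collagen chain, was at 441 ± 57.2 against 0.308 ± 0.106 CPM. Rgs8, a regulator of G protein signalling, rose by 8.39 ± 0.11 and Cspg5, a brain proteoglycan, by 8.01 ± 0.13. Saa3 was at 14.9 ± 1.85 against 36137 ± 1926 CPM and Col3a1, type III collagen, at 13.6 ± 2.58 against 22697 ± 876 CPM. Dpt was at 0.102 ± 0.0559 against 1551 ± 65.2 CPM and Postn at 2.29 ± 0.615 against 3447 ± 239 CPM. Agtr2 changed by -10.05 ± 0.12.

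In the rod list, 24 of 29 members rose, 1 fell and 4 did not pass (camera, adjusted p = 7.98e-10). The member that fell, Reep6, a rod endoplasmic reticulum protein, was at 5.62 ± 0.414 against 41.1 ± 4.57 CPM. Among photoreceptor transcription factors, 11 of 12 members rose and 1 did not pass (adjusted p = 4.25e-06). Of the bipolar list, 9 of 10 members rose and 1 did not pass (adjusted p = 2.02e-05), and of the photoreceptor synapse list, 10 of 13 members rose and 3 did not pass (adjusted p = 0.000107). Of the retinal progenitor list, 11 of 12 members rose and 1 fell (adjusted p = 2.41e-05). The member that fell, Sfrp2, a secreted Wnt antagonist, was at 1.4 ± 0.107 against 409 ± 33.6 CPM. Six3 and Neurog2 were listed at 0 in each of the 3 day 8 libraries, against 129.8 ± 3.37 CPM and 9.79 ± 0.206 CPM in CiPC. For Müller glia genes, 8 of 12 members rose, 2 fell and 2 did not pass (adjusted p = 0.00451). Rlbp1 rose by 8.00 ± 0.12, Gfap, a glial filament protein, was at 50.3 ± 1.6 against 0.0829 ± 0.00508 CPM, and Aqp4 and Abca8a moved against the list. For cone genes, 7 of 10 members rose, 1 fell and 2 did not pass (adjusted p = 0.00609), with Rxrg against the list. Of the proneural list, 7 of 11 members rose and 4 did not pass (adjusted p = 0.00651), and of the pan-neuronal list, 9 of 15 members rose, 1 fell and 5 did not pass (adjusted p = 0.000309), with Nefm against it.

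In the fibroblast list, 1 of 30 members rose, 26 fell and 3 did not pass (adjusted p = 2.15e-13), and Vim, vimentin, was the member that rose (1.86 ± 0.046). Adipocyte genes fell, as all 11 members fell (adjusted p = 6.1e-07), with Fabp4, a fatty acid-binding protein, at 1.6 ± 0.354 against 2526 ± 204 CPM. Among muscle genes, 11 of 12 members fell and 1 did not pass (adjusted p = 3.01e-05). Contractile genes moved the other way from fibroblast genes, as 8 of 12 members rose, 3 fell and 1 did not pass (adjusted p = 0.0496, and adjusted p = 0.142 with an estimated correlation). Tagln was at 914 ± 78.4 against 8.45 ± 1.93 CPM and Acta2, smooth muscle actin, at 2029 ± 23.3 against 72.4 ± 2.77 CPM, while Tpm2, Mylk and Des fell. Of the TGF-beta response genes, 9 of 16 members rose, 1 fell and 6 did not pass (adjusted p = 0.00233, and adjusted p = 0.0621 with an estimated correlation), Ctgf by 5.54 ± 0.065 and Tgfbi by -1.77 ± 0.061. Of the macrophage list, 8 of 14 members rose, 1 fell and 5 did not pass (adjusted p = 0.00222), with Ctss, a lysosomal protease, at 20.5 ± 1.14 against 1.16 ± 0.184 CPM and Cd14 against the list. Cholesterol synthesis genes were called higher with 3 of 17 members rose, 1 fell and 13 did not pass (adjusted p = 0.00661), and cell cycle genes with 2 of 26 members rose, 1 fell and 23 did not pass (adjusted p = 0.00129, and adjusted p = 0.077 with an estimated correlation). The cell cycle member that fell was Ccne1. For amacrine, horizontal and ganglion cells, 7 of 10 members rose, 1 fell and 2 did not pass (adjusted p = 0.0471, and adjusted p = 0.111 with an estimated correlation), with Rbpms against the list. The contractile and amacrine calls were lost under quantile (adjusted p = 0.0743 and adjusted p = 0.0626) and median-of-ratios scaling (adjusted p = 0.0626 and adjusted p = 0.0583).

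The lists of CiPC against day 8 called lower but lost with an estimated correlation were ribosomal proteins, oxidative phosphorylation, p53 and interferon-stimulated genes. In these 12 of 20 members fell and 8 did not pass (adjusted p = 6.51e-05, and adjusted p = 0.0541 with an estimated correlation), 2 of 22 members fell and 20 did not pass (adjusted p = 0.000309, and adjusted p = 0.163 with an estimated correlation), 1 of 14 members rose, 9 fell and 4 did not pass (adjusted p = 0.00251, and adjusted p = 0.0516 with an estimated correlation) and 7 of 17 members fell and 10 did not pass (adjusted p = 0.0227, and adjusted p = 0.077 with an estimated correlation), in that order, and Cdkn1b rose against the p53 list. With limma, 2107 genes were higher in CiPC and 2305 lower (2282 and 2164 under quantile normalization), and 14 of the 22 called lists kept their call with an estimated correlation. Counts adjusted over the list alone equalled those over all genes, and no called list changed direction under another scaling.

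**Figure D3:**
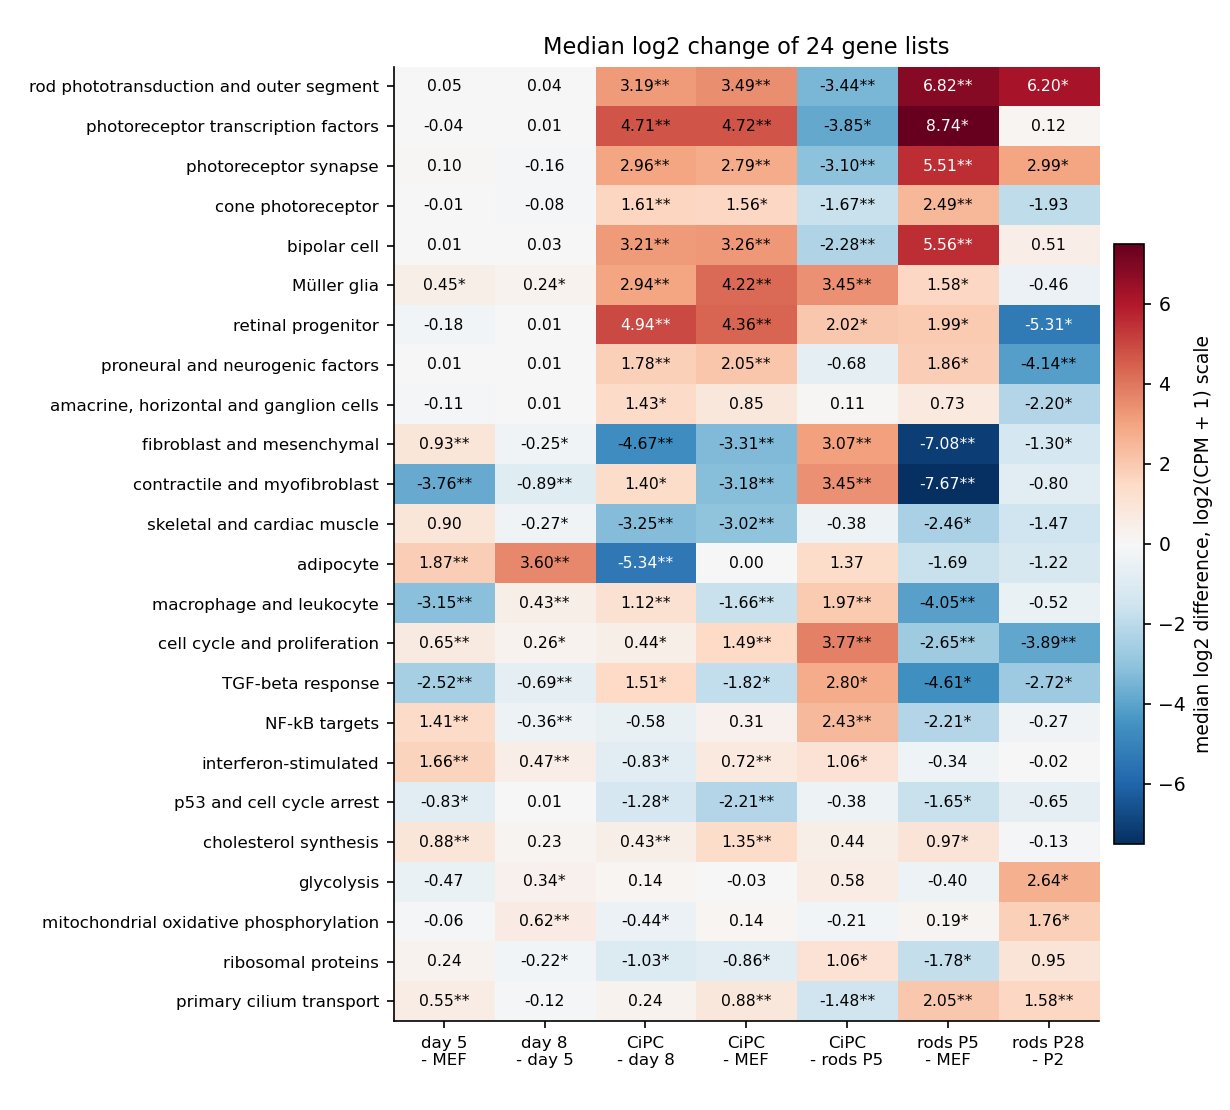
Heat map of the median log2 change on log2(CPM + 1) of 24 gene lists (y axis) in each comparison (x axis); 1 asterisk marks a camera adjusted p under 0.05 and a double asterisk one that also holds with an estimated correlation. Between CiPC and day 8 the rod list has a median of 3.19 and the fibroblast list -4.67; no list called in both scalings differs in sign between the deposited values and quantile normalization, and ribosomal proteins, called with rod age on the deposited values alone, do.

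The comparison of CiPC with P5 rods asked how far the cells at day 11 stood from rods of the same series. Rod and photoreceptor synapse genes were lower in CiPC, and cell cycle, fibroblast, contractile, macrophage, NF-kB target and Müller glia genes were higher. Pde6b, the rod phosphodiesterase beta subunit, was at 15 ± 0.688 against 756 ± 9.99 CPM (n = 3 each). Pitpnm3, a phosphatidylinositol transfer protein, was at 6.83 ± 2.11 against 445 ± 16 CPM and Rp1 at 49.2 ± 4.17 against 1527 ± 112 CPM. Elfn1, a photoreceptor synaptic adhesion protein, was at 1.15 ± 0.431 against 68.1 ± 6.85 CPM, and Doc2b, a calcium sensor of exocytosis, changed by -4.84 ± 0.18. Acta2 was at 2029 ± 23.3 against 3.5 ± 0.649 CPM, Npvf at 690.2 ± 21.3 against 0.804 ± 0.0732 CPM and Tnc at 907 ± 11.3 against 4.5 ± 1.23 CPM. Cyr61, a matricellular protein, was at 976 ± 13 against 4.94 ± 1.18 CPM and Myl9, a myosin light chain, at 324 ± 31.2 against 0.962 ± 0.15 CPM.

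Of the rod list, 29 of 30 members fell and 1 did not pass (camera, adjusted p = 8.04e-12). Over the 27 rod genes at 10 CPM or more in P5 rods, the median CiPC level was 7.19% of the P5 level, from 1.98% for Pde6b to 34.7% for Gnb1. In the photoreceptor synapse list, all 14 members fell (adjusted p = 5.66e-06). Among photoreceptor transcription factors, 11 of 12 members fell and 1 did not pass (adjusted p = 1.05e-05, and adjusted p = 0.0704 with an estimated correlation). Bipolar cell genes were lower than in P5 rods, and 10 of 11 members fell and 1 did not pass (adjusted p = 0.000142). Against the mean of P2, P4 and P6 rods this list was not called, with 4 members that rose and 1 that fell (adjusted p = 0.569). Grm6 was at 35.6 ± 1.11 CPM in CiPC, 215 ± 2.08 in P5, 1.46 ± 0.995 in P4 and 22.8 ± 1.83 in P6 rods. For cone genes, 9 of 12 members fell and 3 did not pass (adjusted p = 0.000923). The median share of the P5 level was 6.85% for the transcription factors, 17.6% for bipolar and 17.9% for cone genes. Of the cilium genes, 1 of 20 members rose, 14 fell and 5 did not pass (adjusted p = 0.000781), with Kif3a against the list. For Müller glia genes, 10 of 11 members rose and 1 did not pass (adjusted p = 0.000178). The 6 of them at 10 CPM or more in P5 rods stood at 279% (Clu) to 3030% (Slc1a3) of P5. Against P2, P4 and P6 rods the median change of this list was 1.84, where it was 3.451 against P5. There, 8 of 11 members rose, 1 fell and 2 did not pass (adjusted p = 0.00225, and adjusted p = 0.291 with an estimated correlation). Of the progenitor list, 7 of 12 members rose, 1 fell and 4 did not pass (adjusted p = 0.0173, and adjusted p = 0.313 with an estimated correlation). Fzd5, a Wnt receptor, was at 215 ± 3.61 against 12.4 ± 0.321 CPM. This call too was absent against P2, P4 and P6 rods, with 1 member that rose and 5 that fell (adjusted p = 0.414).

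In the cell cycle list, all 26 members rose (adjusted p = 2.44e-10), with Rrm2, a ribonucleotide reductase subunit, at 133 ± 14.5 against 0.763 ± 0.208 CPM. Against P2, P4 and P6 rods 19 of the 26 rose (adjusted p = 6.67e-07, and adjusted p = 0.189 with an estimated correlation). Mki67 was at 407 ± 26.8 CPM in CiPC, 4.48 ± 0.484 in P5 and 474 ± 42.8 in P2 rods. In the fibroblast list, 26 of 30 members rose and 4 did not pass (adjusted p = 2.19e-08), with Sparc at 3094 ± 87.1 against 34.2 ± 2.49 CPM. Among contractile genes, 8 of 12 members rose and 4 did not pass (adjusted p = 0.000754). Of the macrophage and leukocyte list, all 14 members rose (adjusted p = 5.83e-05), with Lyz2, lysozyme, at 162 ± 13.5 against 2.15 ± 0.361 CPM. Among NF-kB targets, 17 of 22 members rose, 1 fell and 4 did not pass (adjusted p = 3.39e-05), with Lcn2 at 376 ± 20.4 against 2.7 ± 0.369 CPM and Bcl3 against the list. NRF2 genes were called higher, and 11 of 17 members rose and 6 did not pass (adjusted p = 1.05e-05, and adjusted p = 0.0704 with an estimated correlation), with Hmox1, heme oxygenase, at 331 ± 11.4 against 9.13 ± 0.0845 CPM. Of the TGF-beta response genes, 13 of 16 members rose, 1 fell and 2 did not pass (adjusted p = 7.91e-05, and adjusted p = 0.113 with an estimated correlation), with Skil against the list. The remaining calls, all higher, were lost with an estimated correlation (adjusted p = 0.0741 to adjusted p = 0.152). They were ribosomal proteins (11 of 20 rose), cAMP and CREB targets (8 of 14), interferon-stimulated genes (9 of 17) and housekeeping genes (4 of 13).

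With limma, 3369 of 14333 genes were higher in CiPC than in P5 rods and 2501 lower (57.4% higher). Under quantile normalization 2876 were higher and 3403 lower (45.8%), and the median of all genes moved from 0 to -0.17. On the deposited values, list medians were thus already relative to the median of all genes. With the mean of P2, P4 and P6 rods of the older series in place of P5, 3756 of the 5870 calls (63.99%) stayed in the same direction and 63 turned. Of the 19 called lists, 15 kept their call in the same direction against these older-series rods and 4 lost it. Another 5 lists were called against these rods alone. Cholesterol synthesis and p53 genes were higher in CiPC there. Proneural, pan-neuronal and amacrine, horizontal and ganglion cell genes were lower. With an estimated correlation 0 of the calls against these rods held. No called list changed direction under another scaling, counts adjusted over the list alone equalled those over all genes, and 11 of the 19 lists called against P5 kept their call with an estimated correlation.

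P5 rods were compared with MEF to give the change between fibroblasts and rods. Photoreceptor genes were higher in rods and fibroblast genes lower. Rbp3, the retinoid carrier of the interphotoreceptor matrix, was at 4234 ± 162 against 0.695 ± 0.268 CPM (n = 3 each). Pdc was at 1676 ± 22 against 0.0868 ± 0.0784 CPM and Crx at 1664 ± 45.8 against 0.391 ± 0.197 CPM. Prph2 rose by 10.31 ± 0.10 and Rp1 by 10.13 ± 0.083. Thbs1, thrombospondin, was at 2.81 ± 0.183 against 14400 ± 220.3 CPM. Col1a1 was at 1.95 ± 0.236 against 4545 ± 622 CPM and Acta2 at 3.5 ± 0.649 against 6741 ± 39.8 CPM. Bgn, the proteoglycan biglycan, was at 0.396 ± 0.154 against 1980 ± 7.69 CPM. With limma, 3452 genes were higher in P5 rods and 4297 lower (44.55% higher). Under quantile normalization 4083 were higher and 3740 lower (52.19%), and the median of all genes moved from -0.09 to 0.10, so which direction held more genes depended on the scaling.

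Of the rod list, all 30 members rose (camera, adjusted p = 1.54e-12), with a median of 6.91 relative to all genes. Of the fibroblast list, all 30 members fell (adjusted p = 1.01e-10), with a relative median of -6.99. Photoreceptor synapse (adjusted p = 2.23e-06), bipolar (adjusted p = 1.85e-05), cone (adjusted p = 0.00012) and cilium (adjusted p = 4.49e-05) lists were called higher in P5 rods. Cell cycle (adjusted p = 3.13e-06), contractile (adjusted p = 7.16e-06) and macrophage (adjusted p = 5.31e-05) lists were called lower. Lists called higher with the preset correlation alone were photoreceptor transcription factors, proneural factors, Müller glia, progenitor, cholesterol and oxidative phosphorylation genes (adjusted p = 0.0549 to adjusted p = 0.389 with an estimated correlation). Dkk3 fell against the Müller glia list and Sfrp2 against the progenitor list. Lists called lower with the preset correlation alone were TGF-beta response, ribosomal protein, NRF2, muscle, NF-kB, p53, epithelial and stress response genes (adjusted p = 0.0549 to adjusted p = 0.167 with an estimated correlation). Bcl3, Sod2 and Lcn2 rose against the NF-kB list, Cdkn1b against the p53 list and Atf3 against the stress response list. No list called changed direction under another scaling. The lists kept with an estimated correlation numbered 9 of 23, and counts adjusted over the list alone equalled those over all genes.

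Across 14333 genes, the changes of CiPC and of P5 rods from MEF were correlated (Pearson r = 0.70), genes not being independent replicates. Fibroblast genes such as Col1a1 and Lox were lower in both, and rod genes such as Pdc and Prph2 higher in both, with smaller changes in CiPC. The covariance was 2.18, against 0.00777 in 100 simulations of unchanged groups sharing simulated MEF means, a difference of 2.17. The simulated r was 0.50. Genes higher in both numbered 1342 (549.4 for independent lists) and lower in both 1980 (708.1). Another 308 genes were higher in CiPC and lower in rods (683.8), and 26 were lower in CiPC and higher in rods (568.9). By the simulations, the spread between replicates, pooled over MEF, CiPC and P5 rods, gives little of the covariance. A deviation common to all 3 MEF libraries is not in that spread, and they could not be split with 2 in each part. Some of the excess may therefore still come from the shared controls. As the simulated groups were unchanged, the excess also holds any loss of fibroblast genes in both.

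**Figure D4:**
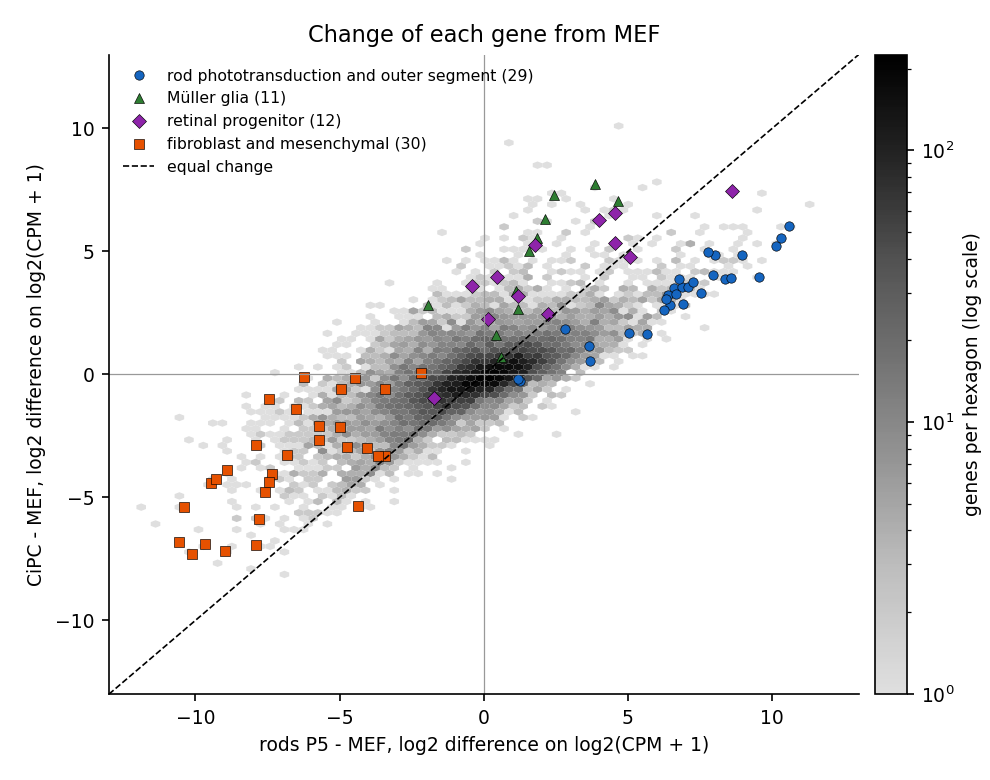
Hexagons count genes by their log2 change on log2(CPM + 1) from MEF in P5 rods (x axis) and in CiPC (y axis), with members of 4 lists marked and a dashed line of equal change. Rod genes lie below the line and Müller glia genes above it, with list medians of 6.82 in rods and 3.49 in CiPC for rod genes and 1.58 and 4.22 for Müller glia; no scaling turned these directions.

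The age of the isolated rods was examined over the 18 libraries of P2, P4, P6, P10, P14 and P28, as a slope on log2 age and as P28 against P2. Phototransduction genes rose with age, and cell cycle, progenitor and proneural genes fell, though in the slope these lists were called with the preset correlation alone. Gnat1, rod transducin, was at 69103 ± 7367 against 9.07 ± 0.935 CPM in P28 (n = 4) and P2 (n = 2) rods. Slc24a1, the rod cation exchanger, was at 10055 ± 821 against 0.826 ± 0.0159 CPM and Guca1b, a guanylate cyclase activator, at 6231 ± 1675 against 0.907 ± 0.0502 CPM. Pde6a was at 15369 ± 1017 against 6.84 ± 1.89 CPM. Kcnj14, a potassium channel, rose by 12.49 ± 0.97 over the age range. Epha8, an ephrin receptor, was at 0.321 ± 0.308 against 397 ± 50.5 CPM and Nnat, neuronatin, at 0.523 ± 0.235 against 348 ± 73.5 CPM. Ccnd1, cyclin D1, was at 3.98 ± 1.57 against 1078 ± 79.9 CPM and Top2a at 0.226 ± 0.303 against 397 ± 27.6 CPM. Mki67, the proliferation antigen, was listed at 0 in each of the 4 P28 libraries and was at 474 ± 42.8 CPM in P2. Nrl rose by 4.23 ± 0.45 over the age range. For Crx and Nr2e3 the changes were 1.45 ± 0.20 and 1.29 ± 0.32 on the deposited values and -1.31 and -1.32 under quantile normalization.

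None of the list calls of the slope held with an estimated correlation. In the rod list, all 30 members rose (camera, adjusted p = 1.36e-19, and adjusted p = 0.27 with an estimated correlation), with a median of 7.22 relative to all genes. Of the glycolysis genes, 17 of 21 members rose and 4 did not pass (adjusted p = 2.6e-07, and adjusted p = 0.402 with an estimated correlation), with Hk2, a hexokinase, at 1718 ± 184 against 21.7 ± 2.23 CPM. Of the photoreceptor synapse list, 11 of 14 members rose, 1 fell and 2 did not pass (adjusted p = 6.3e-06, and adjusted p = 0.27 with an estimated correlation), Bsn, bassoon, against it. Of the oxidative phosphorylation genes, 19 of 22 members rose and 3 did not pass (adjusted p = 6.3e-06, and adjusted p = 0.542 with an estimated correlation). Of the cilium genes, 13 of 21 members rose, 2 fell and 6 did not pass (adjusted p = 0.000141, and adjusted p = 0.27 with an estimated correlation), with Rpgr and Nphp4 against the list. In the cell cycle list, 24 of 26 members fell and 2 did not pass (adjusted p = 6.49e-07, and adjusted p = 0.51 with an estimated correlation), with a relative median of -3.50. Among proneural factors, all 15 members fell (adjusted p = 1.79e-06, and adjusted p = 0.27 with an estimated correlation), Neurod4 by -8.38 ± 0.75. Among progenitor genes, 12 of 13 members fell and 1 did not pass (adjusted p = 2.96e-06, and adjusted p = 0.206 with an estimated correlation), Notch1 by -7.45 ± 0.49. Other falling lists were TGF-beta response with 11 of 13 members (adjusted p = 0.000255, and adjusted p = 0.402 with an estimated correlation) and amacrine, horizontal and ganglion cells with 7 of 12 (adjusted p = 0.00897, and adjusted p = 0.441 with an estimated correlation). The calls of fibroblast genes, of which 12 of 22 fell (adjusted p = 0.011, and adjusted p = 0.542 with an estimated correlation), and of glial genes, of which 4 of 6 fell (adjusted p = 0.0419, and adjusted p = 0.46 with an estimated correlation), were lost under quantile normalization (adjusted p = 0.0924 and adjusted p = 0.123). Among ribosomal protein genes, 10 of 20 members rose and 10 did not pass (adjusted p = 0.0315, and adjusted p = 0.861 with an estimated correlation), but under quantile normalization their direction turned (adjusted p = 0.345).

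With limma, 2978 of 13884 genes rose with age and 4520 fell (39.7% higher). Under quantile normalization 3472 rose and 3252 fell (51.6%), and the median of all genes moved from -0.31 to 0.07 (-0.19 with median-of-ratios scaling). Between P28 and P2, 2739 genes were higher and 4305 lower (38.9%), against 3211 and 2957 under quantile normalization (52.1%). The median of all genes moved from -0.29 to 0.08 there (-0.18 with median-of-ratios scaling). In P28 against P2, 13 of 41 lists were called, and those of the cell cycle (adjusted p = 1.52e-10), the proneural factors (adjusted p = 8.47e-08) and the cilium (adjusted p = 0.000198) held with an estimated correlation. The calls of oxidative phosphorylation (adjusted p = 0.056), fibroblast (adjusted p = 0.0673) and canonical Wnt genes (adjusted p = 0.218) were lost under quantile normalization. The pluripotency list had 1 member higher and 2 lower of 3 (adjusted p = 0.956). Its higher member was Esrrb, a nuclear receptor also made by rods (9.71 ± 0.21). None of the 4 red blood cell genes passed (adjusted p = 0.773). Adjusted over the list alone, 0 ribosomal protein genes passed between P28 and P2 where 4 rose over all genes, and 0 macrophage genes where 1 fell. In the slope 6 housekeeping genes rose where 5 did over all genes, and 1 pigment epithelium gene fell where 2 did.

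The 200 genes with the strongest rise and the 200 with the strongest fall over rod age were then followed in CiPC. Both sets were higher in CiPC than in MEF. Among rising genes, 77 of 191 rose and 19 fell (median 0.66; camera, adjusted p = 0.000246, and adjusted p = 0.0877 with an estimated correlation). Of the falling genes, 86 of 197 rose and 32 fell (median 0.60; adjusted p = 0.000246, and adjusted p = 0.117 with an estimated correlation). Against P5 rods, 117 of 199 rising genes were lower in CiPC and 13 higher (median -1.42; adjusted p = 1.24e-13). There, 135 of 197 falling genes were higher and 8 lower (median 2.19; adjusted p = 7.06e-16). Between CiPC and day 8 both sets were again higher. Among rising genes, 72 of 191 rose and 23 fell (median 0.345; adjusted p = 0.00181), and among falling genes 91 of 197 rose and 22 fell (median 0.775; adjusted p = 3.82e-06). Both calls were lost with an estimated correlation (adjusted p = 0.0833).

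P5 rods, the only rod group analysed here with no older sample listed, were set against the mean of P4 and P6 rods of the older series, whose mean age is also 5 days. Cholesterol synthesis, bipolar cell and interferon-stimulated genes were higher in P5 rods, and cell cycle, cone and progenitor genes were lower, all called with the preset correlation alone. Fgf2, a fibroblast growth factor, was at 226 ± 21.6 against 3.62 CPM (P5, n = 3; P4, n = 2; P6, n = 3). Cdkn1a was at 208 ± 4.63 against 4.35 CPM and Sspo, SCO-spondin, at 57 ± 3.71 against 0.501 CPM. Kcng4, a potassium channel, was at 48 ± 2.54 against 0.308 CPM and Lad1 at 46.9 ± 1.98 against 0.344 CPM. Opn1sw, the short-wavelength cone opsin, was at 3.66 ± 0.496 against 111 CPM and Mki67 at 4.48 ± 0.484 against 143 CPM. Abca1, a cholesterol exporter, was at 6.8 ± 0.805 against 171 CPM. Moxd1 was at 1.09 ± 0.245 against 40.9 CPM and Ndufa4l2 at 0.694 ± 0.281 against 33.3 CPM. Rcvrn was at 269 ± 19 against 75 CPM.

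In the cell cycle list, 22 of 26 members fell and 4 did not pass (camera, adjusted p = 1.31e-08, and adjusted p = 0.416 with an estimated correlation). Of the cholesterol synthesis genes, 14 of 16 members rose and 2 did not pass (adjusted p = 1.31e-08, and adjusted p = 0.193 with an estimated correlation). For interferon-stimulated genes, 10 of 12 members rose and 2 did not pass (adjusted p = 1.28e-05, and adjusted p = 0.193 with an estimated correlation). Of the bipolar list, 8 of 11 members rose and 3 did not pass (adjusted p = 0.00015, and adjusted p = 0.193 with an estimated correlation), with Grm6 at 215 ± 2.08 against 12.1 CPM. For cone genes, 2 of 13 members rose, 8 fell and 3 did not pass (adjusted p = 0.00916, and adjusted p = 0.523 with an estimated correlation), with Gnb3 and Kcne2 against the list. For Müller glia genes, 1 of 11 members rose, 7 fell and 3 did not pass (adjusted p = 0.0314, and adjusted p = 0.705 with an estimated correlation), with Clu against the list. Of the p53 genes, 7 of 11 members rose, 1 fell and 3 did not pass (adjusted p = 0.00595, and adjusted p = 0.193 with an estimated correlation), with Cdkn1b against the list. Of the progenitor list, 1 of 13 members rose, 11 fell and 1 did not pass (adjusted p = 0.00194, and adjusted p = 0.573 with an estimated correlation). Among proneural factors, 11 of 15 members fell and 4 did not pass (adjusted p = 0.000849, and adjusted p = 0.44 with an estimated correlation). The other calls (adjusted p = 0.523 to adjusted p = 0.537 with an estimated correlation) were lower for amacrine, horizontal and ganglion cells (8 of 12 fell) and TGF-beta response genes (6 of 14). They were higher for oxidative phosphorylation (2 of 22 rose) and the stress response (6 of 16 rose, and Dnajb9 fell), the last lost under quantile normalization (adjusted p = 0.0538). The rod list was not called, and 4 of 30 members rose, 4 fell and 22 did not pass (adjusted p = 0.308). Nor was the immediate early and dissociation list, of which 3 of 16 members rose, 8 fell and 5 did not pass (adjusted p = 0.483). Fos was at 23.6 ± 2.06 against 386 CPM, and Atf3, Hspa1a and Hspa1b rose. Mitochondrially encoded genes took 1.96% to 2.57% of the P5 libraries and 4.37% to 8.91% of the P4 and P6 libraries. Whether sample handling differed was not tested.

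With limma, 1122 of 13652 genes were higher in P5 and 1788 lower (38.56% higher). The excess of lower genes was smaller under quantile normalization, with 1357 higher and 1464 lower (48.1%), and with median-of-ratios scaling, with 1280 and 1582. No call of the 13 lists held with an estimated correlation, none changed direction under another scaling, and counts adjusted over the list alone equalled those over all genes. Series and age group cannot be told apart here, because the P5 libraries came from one series and the P4 and P6 libraries from the other, and this bears on the comparisons of CiPC and MEF with rods.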

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

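The tests in this part were chosen after the result was seen, except the counts over other splits of the libraries. The removal of a GC content and transcript length trend was added after the data were seen, but its bounds for the P5 rods were set before its result was seen. Of 22 values tested in groups of 4 libraries, 2 held a library far from the others, and chance alone marks about 1 in 20. Crx in P10 rods was at 2219 CPM in replicate 2, against 2028 to 2060 in the others. Axin2 in P10 rods was at 17.7 CPM in replicate 4, against 9.852 to 10.57 in the others.

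CiPC held rod, retinal progenitor, Müller glia, bipolar and contractile transcripts together. The tables argue against unconverted cells with the average day 8 profile as the source of the contractile genes that rose. Such cells bring no gene above its day 8 level. A subset of day 8 cells, or cells that changed after day 8, could differ from that profile, and neither was tested. Of all 12 contractile genes, 8 rose against day 8, Acta2 from 72.4 to 2029 CPM, and 3 fell (median log2 change 1.404, and a median level of at least 336% of day 8). Of those that fell, Tpm2 kept 24.6% and Mylk 40.6% of the day 8 level. For 23 abundant fibroblast genes the median was at most 2.09% (0.0597% for Col3a1 to 53.7% for Fstl1), and for 14 Hox genes at most 0.27%. These values argue against a remnant with the average day 8 profile as the main source of Tpm2 and Mylk. For Des, at 1.14%, a remnant stays open. At 10 CPM or more in every CiPC library and above every MEF, day 5 and day 8 library were 9 of 12 Müller glia (75%), 9 of 13 progenitor, 5 of 11 bipolar and 2 of 14 cone genes, but 0 of 12 amacrine, horizontal and ganglion and 0 of 8 pigment epithelium genes. These counts cannot part other retinal cells from a mixed retinal state of the reprogrammed cells, which were sorted by the reporter, and neither was tested further.

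P5 rods stood apart from P4 and P6 rods of the older series, with 2910 genes past the threshold. Age as the whole cause is argued against by the rod-age sets, since genes falling with age had a median of -1.05, which by the age slopes needs one of 0.889 in the rising genes, where it was 0.141 (quartiles -0.502 to 0.628). A lower share of rods in the P5 sort, with more of all other retinal cells together, would raise the markers of each. Medians were -2.14 for cone, -1.15 for Müller glia and -1.41 for amacrine, horizontal and ganglion genes, but 2.34 for bipolar genes. These values argue against a rise of all other cells together. They cannot decide about a shift in a single cell type, such as bipolar cells. A higher share of rods in the P5 sort, which would lower the markers of all other cells together, was not tested. With a GC content and transcript length trend removed, 65% of the called genes stayed past the threshold in the same direction, and Spearman's rho between change and GC content went from 0.436 to 0.024. GC content as a cause of part of the pattern therefore cannot be told apart from other differences between the series, with which age group is confounded, although 8 cone genes fell before and after the removal.

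P10 replicate 4 and P14 replicate 3 stood apart from the other libraries of their ages on the second principal component. A younger age than the label would lower genes that rise with age and raise those that fall. In sets taken from a fit without both libraries, rising genes had medians of -0.483 in P10 replicate 4 and -0.461 in P14 replicate 3, and falling genes at 10 CPM or more in the other libraries of the age went both ways, with medians of 0.196 (quartiles -0.122 to 0.553, 56 genes) and -0.369 (-0.81 to 0.000374, 33 genes). Differences from the other libraries correlated with transcript length, with a rho of 0.228 in P10 replicate 4 (at most 0.0392 in the others) and 0.22 in P14 replicate 3 (at most -0.094). Neither a younger age nor an effect of transcript length, whose values lie between the bounds set, can be told apart from other causes, and no biological explanation was tested.

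Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real split, counted as 1, called 4641 genes between CiPC and MEF (highest other 0), 3873 between day 5 and MEF (0), 878 between day 8 and day 5 (0) and 4412 between CiPC and day 8 (1). For CiPC against P5 rods the numbers were 5870 and 0, and for P5 rods against MEF 7749 and 0. Over the age slope, 1 of 100 splits, the real one, called as many genes (7498, highest other 3073). Ages were shuffled over single libraries there, and libraries of an age may not be independent, so chance cannot be excluded. For P5 rods against P4 and P6 rods it was likewise 1 of 100 (2910, highest other 2817). That share is under 0.05, but single libraries were relabelled, and these may not be independent, so chance cannot be excluded. In 3 of the splits, the real one included, the P5 libraries stayed together (highest other 2817), and splits that parted them called at most 559. The count therefore followed whether the P5 libraries stayed together.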

How the results depend on the processing

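Alternatives added after the data were seen were the fits without P10 replicate 4 and P14 replicate 3, P5 rods against the mean of P2, P4 and P6, and the removal of a GC content and transcript length trend, whose bounds for the P5 rods were set before its result was seen. Over 42 results and 520 alternatives, 467 values kept their direction and size or side of the threshold, 51 moved and 2 weakened. For 157 changes of named genes, 99.56% of 2988 values stayed the same, 6 were stronger, 3 weaker and 4 reversed. Causes were not tested except where a setting itself changes how many genes can pass. Without the fold threshold, higher and lower genes numbered 5363 and 5991 (CiPC against MEF), 5543 and 5368 (day 5 against MEF), 3436 and 3269 (day 8 against day 5), 5253 and 5820 (CiPC against day 8), 6035 and 6009 (CiPC against P5 rods), 6103 and 6679 (P5 rods against MEF) and 3970 and 4984 (P5 against P4 and P6 rods). A pseudocount of 0.1 gave 735 lower genes between day 8 and day 5, and a pseudocount of 3 gave 215. With an estimated correlation, lists called lower numbered 5 in CiPC against MEF and 3 in CiPC against day 8, and lists called higher 6 in CiPC against P5 rods. Lists called higher and lower numbered 5 and 3 in day 8 against day 5, 5 and 4 in P5 rods against MEF, 1 and 2 in P28 against P2, and 0 and 0 in both P5 against P4 and P6 rods and the age slope. The rod-age sets lost their call in CiPC against MEF (adjusted p = 0.0877 for rising and adjusted p = 0.117 for falling genes). For the changes of CiPC and rods, r was 0.7372 with a pseudocount of 0.1, 0.7271 with rods of P2, P4 and P6 and 0.68 under quantile normalization. It ran from 0.6798 to 0.7058 with each library left out. The covariance was 3.798 with a pseudocount of 0.1, 2.422 at a CPM of at least 5, 2.161 with rods of P2, P4 and P6, 2.08 under quantile normalization and 2.007 to 2.236 with each library left out. Under quantile normalization directions reversed for Crx in rods P28 vs P2 (-1.005), Nr2e3 in rods P28 vs P2 (-0.9617), Crx in rod age slope (-1.313) and Nr2e3 in rod age slope (-1.322). Leaving out P10 replicate 4 and P14 replicate 3 gave 3107 rising and 4694 falling genes in the slope, and P5 rods against the mean of P2, P4 and P6 gave 1126 higher and 1863 lower.

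Libraries of different groups share only a replicate number. Same-number libraries did not deviate together, with correlations from -0.421 (CiPC against day 8) to 0.18 (P5 rods against MEF), and in no comparison was every library closest to its own number. With the replicate block, 4642 genes were called in CiPC against MEF, 3873 in day 5 against MEF, 878 in day 8 against day 5, 4412 in CiPC against day 8, 5870 in CiPC against P5 rods and 7748 in P5 rods against MEF. In the comparisons of rods it gave 7478 for P28 against P2 and 2884 for P5 against P4 and P6. It moved no count of genes by more than 1.5 times, and day 5 against MEF, day 8 against day 5 and CiPC against day 8 each called 1 list fewer. The depth behind the deposited values is unknown, so what it limits was not assessed. Alternatives that need the P3 libraries were not run, because the table holds no such columns.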

Other observations

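The tests in this part were all chosen after the result was seen. Hox genes, which set body position and were not among the lists fixed before the data were examined, were present in the cultured cells and near 0 in CiPC. Over 35 Hox genes, mean levels summed to 252.8 CPM in MEF, 259.6 at day 5 and 220.0 at day 8, against 0.8039 CPM in CiPC and 2.983 in P5 rods. By group means, in MEF 34 of them stood at 1 CPM or more, at day 5 and day 8 33 did, and in CiPC and rods 0 did. In single libraries 30 to 31 did at day 8, 0 in CiPC and at most 1 in rods. Tbx15, a mesenchymal transcription factor, was at 44.71 ± 1.9 CPM in MEF, 142.5 ± 4.38 at day 8 and 1.111 ± 0.0324 in CiPC (mean ± SD, n = 3). Igf2, an insulin-like growth factor, was at 4823 ± 260, 6995 ± 402 and 78.21 ± 7.06 CPM.

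Some transcripts were at higher levels in CiPC than in any other group. Aldh1a1, a retinaldehyde dehydrogenase of the retina, was at 641.8 ± 55.5 CPM in CiPC, 35.45 ± 0.413 at day 8 and at most 38.37 ± 0.0373 in rods (P2, n = 2). F5, coagulation factor V, was at 362.5 ± 24.9 CPM in CiPC and 5.827 ± 0.0728 in MEF. Crym, Npvf and Cp were at 3113 ± 73.4, 690.2 ± 21.3 and 3211 ± 348 CPM in CiPC. In the next highest group they were at 187.4 ± 45.4 (P6 rods), 0.8044 ± 0.0732 (P5 rods) and 176.6 ± 13 CPM (day 8).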
